A study of Caenorhabditis elegans with 8 samples.

How the data were processed

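Total RNA of mixed-stage Caenorhabditis elegans was extracted with TRIZOL, labelled with biotin and hybridised to 1-colour Affymetrix C. elegans Genome Arrays, per the labels' protocols. The labels put 4 arrays in the ercc-1 mutant group and 4 in the wild type N2 group. The authors deposited 1 table with 1 value per probe set and array, which is read here as log2 expression. The log base is not stated. It was inferred from the values, which run from 0 to 14.38 with 2 decimals, the range of the log2 of a 16-bit scanner signal. Per the submitters' processing notes the tool was Affymetrix Expression Console 1.1. The summarisation and normalization algorithms are not given in the sources used here, and no background level or detection call was used. The arrays' sorted values were not identical, so the table was not exactly quantile normalized, and no further normalization was applied for the main results.

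Probe sets were named through the platform annotation, which paired 20766 probe sets with 1 gene, 887 with several and 895 with none. The gene identifiers of 20701 of the single-gene probe sets were found in a RefSeq gene table (assembly WBcel235), which changed 0 symbols. That table was used only for names, chromosomes and neighbours, since the array design is not known to follow its build. No gene was named from a probe set with several genes. Where a gene had several probe sets, the one with the highest mean over all 8 arrays stood for it, which left 17118 genes.

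Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups of 4, two-sided moderated test, Benjamini-Hochberg adjustment over 22548 probe sets). A probe set was called at an adjusted p under 0.05, with no fold minimum. All fold changes are mutant minus wild type on the log2 scale. For 30 gene lists, limma's camera was run with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, with camera's estimated correlation and limma's fry beside it. The camera test compares a list with all other measured genes, and the mean log2 change over all genes was 0.05. Its direction, up or down, is thus relative to the other genes and not to wild type. Of the members written into the lists, 38 matched no measured gene. Similarity of arrays was tested with an exact permutation test over the 35 splits into 4 and 4, and called genes by chromosome with Fisher's exact test. The tests, the gene lists, the alternatives and the rule for named genes were set before the data were examined, except where a choice is said to have been made afterwards. The rule names ercc-1, the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap, and the members of each list with the smallest p, up to 4 for a list with a called member and up to 2 otherwise. All genes that the rule gives are named.

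The fit and the list test were tested on simulated data of 22548 probe sets with 200 changed, in 10 data sets of the size of the mutant and wild-type comparison. The fit recovered 50.5% of changes of 0.5 on the log2 scale, 96.3% of changes of 1 and 99.8% of changes of 2, and 4.3% of its calls were false. The simulated noise was independent between probe sets and had the same spread in both groups. The real arrays had a median SD of 0.154 in the mutant and 0.113 in wild type, so these rates may not hold for them. The shifted list was found in 100% of the data sets, and 0% of the unshifted lists were called. That rate does not carry over to these arrays, where the list test with the preset correlation called between 2 and 20 of the 30 lists in the other splits of the 8 arrays.

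The alternatives were quantile normalization, median centring, leaving out the dimmest 25% of probe sets, leaving out probe sets with the suffix _x_at or _s_at (which can match several transcripts), a trended robust variance, array weights, the replicate number as a block, other thresholds, other list tests and leaving out each array in turn. Leaving out mutant replicates 1 and 4 together, and leaving out each array in the chromosome test, were added after seeing the data. For arrays, the number per group (n = 4) limits the precision.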

Results

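Transcript levels were measured in Caenorhabditis elegans, a nematode, in cultures that held all stages of the life cycle. RNA of worms mutant for ercc-1 was hybridised to 4 arrays, and RNA of wild type N2, the standard laboratory strain and the background of the mutant, to 4 others. ERCC-1 is a subunit of the endonuclease that cuts the damaged strand in nucleotide excision repair, and the labels describe the mutant as deficient in that pathway. Both strains were fed for 3 to 4 days on Escherichia coli HT115(DE3) carrying pL4440, a plasmid commonly used as the empty vector in RNA interference by feeding. Each array gave log2 values for 22548 probe sets. The median log2 value was 7.59, 7.52, 7.44 and 7.5 on mutant replicates 1 to 4, and 7.44, 7.39, 7.44 and 7.42 on wild-type replicates 1 to 4. Between 0 and 4 values per array were listed at 0. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

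The mutant arrays varied more among themselves than the wild-type arrays did. The median SD of a probe set was 0.154 over the mutant arrays and 0.113 over the wild-type arrays (n = 4 each). Correlations between pairs of arrays ran from 0.9776, for mutant replicates 1 and 4, to 0.9957, for wild-type replicates 2 and 4. Their mean was 0.9901 within groups (0.9865 among mutant arrays and 0.9937 among wild-type arrays) and 0.9883 between groups. Mutant arrays thus correlated less with each other than with wild-type arrays, and the higher mean within groups came from the wild-type arrays. That difference of 0.00181 was reached by 3 of the 35 splits of the arrays (exact permutation test, one-sided, p = 0.0857), so the groups were not separated over all probe sets by this test. Leaving out mutant replicate 1, 2 or 3 gave differences of 0.00267, 0.00301 and 0.00348 (exact p = 0.0286 each), leaving out mutant replicate 4 gave 0.00295 (exact p = 0.0571), and leaving out wild-type replicate 1, 2, 3 or 4 gave 0.00095, 0.00048, 0.00039 and 0.00057 (exact p from 0.286 to 0.371). The first principal component held 35.6% of the variance, with mutant replicate 1 at -35.9 and mutant replicate 4 at 24.6.

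**Figure D1:**
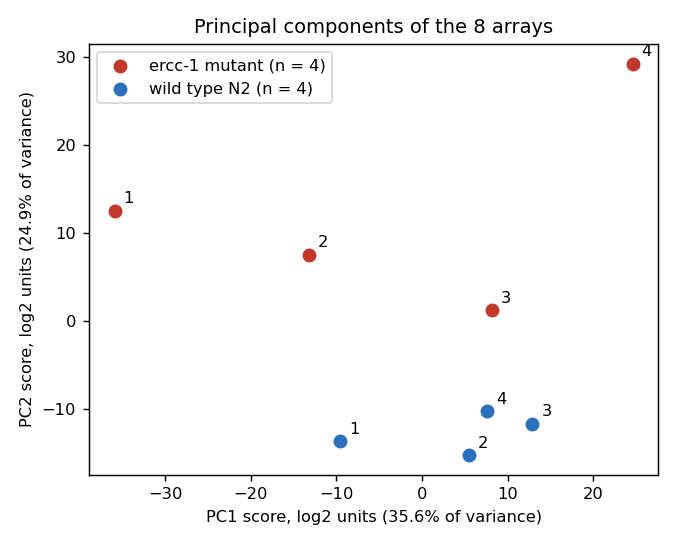
Scores of the 8 arrays on the first (x axis, 35.6% of the variance) and second principal component (y axis, 24.9%), in log2 units, with replicate numbers beside the points. Mutant replicates 1 and 4 lie farthest apart on the x axis, at -35.9 and 24.6, and the 4 mutant arrays lie above the 4 wild-type arrays on the y axis.

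The ercc-1 transcript itself was measured at similar levels in both groups. Its probe set read 9.84 ± 0.074 in the mutant and 9.85 ± 0.124 in wild type (SD, n = 4 each). The log2 difference was -0.015 (SE 0.081, 95% confidence interval -0.198 to 0.168), with p = 0.857 in an exact two-sided permutation test over 70 assignments, where the smallest possible p is 0.0286. The difference turned to 0.014 without mutant replicate 2 and 0.041 without wild-type replicate 3, and was -0.046 without mutant replicate 4 and -0.053, -0.039 and -0.009 without wild-type replicates 1, 2 and 4. The labels do not name the allele and the position of the probes within the gene is not known here, so this probe set does not check the labels, and "mutant" below means the arrays labelled ercc-1 mutant.

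The comparison of mutant with wild type asked which transcripts differ when ERCC-1 is impaired, in a study of DNA repair and replicative ageing. The largest difference was a fall of hrg-11.2, which read 7.55 ± 0.287 in the mutant and 11.23 ± 0.168 in wild type (SD, n = 4 each), a 12.8-fold lower level (adjusted p = 1.18e-05). The transcript of nlp-12, which encodes a neuropeptide-like protein, was 4.22-fold lower (log2 difference -2.08, SE 0.142, adjusted p = 0.000378). The transcript of fcd-2, the orthologue of the Fanconi anaemia gene FANCD2, was 2.02-fold lower (-1.02, SE 0.069, adjusted p = 0.000378), and cls-3, of the CLASP family of microtubule-binding proteins, was 2.07-fold lower (-1.05, SE 0.136, adjusted p = 0.0127). These were the 4 calls at least 2-fold lower, against 58 at least 2-fold higher. All 4 were read by probe sets with the suffix _s_at, which can match several transcripts. They were therefore not in the fit that left out _x_at and _s_at probe sets. The other large falls were those of ugt-64, a UDP-glucuronosyltransferase (-0.83), T10D4.6 (-0.67), lido-5 (-0.66), F25H9.2 (-0.62), fbxb-97 (-0.59) and F19B10.2 (-0.58), with adjusted p from 0.0093 to 0.0375. The second probe sets of T10D4.6 and F19B10.2 read -0.42 and -0.42 (adjusted p = 0.0381 and 0.188). Without any 1 of the wild-type replicates, adjusted p rose past the threshold for cls-3 (0.0572 to 0.0709), lido-5 (0.0572 to 0.063), F25H9.2 (0.0511 to 0.0587), fbxb-97 (0.0599 to 0.0641) and F19B10.2 (0.1 to 0.154, and 0.0985 without mutant replicate 2). The same happened for T10D4.6 without wild-type replicate 1, 2 or 4 (0.0572 to 0.0637) and for ugt-64 without wild-type replicate 2 or 4 (0.0511 and 0.0555), while hrg-11.2, nlp-12 and fcd-2 stayed past it in all 8 fits that left out 1 array.

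Among the transcripts that rose, K12H6.4 had the largest change, 4.92-fold (log2 difference 2.3, SE 0.184, adjusted p = 0.000995). It was followed by clec-137, which encodes a protein with a C-type lectin domain (4.71-fold, adjusted p = 0.00579), C09G12.5 (4.35-fold, adjusted p = 0.000442), ZK1290.11 (3.94-fold) and F59B2.12 (3.84-fold). The other large rises were fipr-17 (3.36-fold) and fipr-16 (3.28-fold), named as fungus-induced protein related, K12H6.9 (3.36-fold), srj-29, a serpentine receptor class gene (3.23-fold), and clec-219 (3.12-fold). All 10 had mean wild-type values below 6.42, the bound of the dimmest 25% of probe sets by mean, and no background level was known for them. All 10 stayed past the threshold in each of the 8 fits that left out 1 array. Those of ZK1290.11, fipr-17, fipr-16 and K12H6.9 were read by probe sets with the suffix _x_at or _s_at, which can match several transcripts.

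In all, 150 of 22548 probe sets passed the threshold, 121 higher and 29 lower in the mutant, and 2225 had an unadjusted p under 0.05. At the level of genes, 115 of 17118 passed, 91 higher and 24 lower. The 4 mutant values lay on one side of the 4 wild-type values in all 150 calls, and in 6.48% of all probe sets, against 2.86% by chance. Among the calls, 80.7% were higher, and 64.7% (75 higher, 41 lower) after each array was centred on its median, which lowers every log2 difference by 0.09. The number of calls was 37, 29, 34 and 31 without wild-type replicate 1, 2, 3 and 4, and 89, 80 and 268 without mutant replicate 1, 2 and 4. It was 46 without the probe sets whose suffix marks possible matches to several transcripts, which made up 80 of the 150, and 1423 with array weights. Those weights were 5.05 for mutant replicate 2 and 0.62, 0.46 and 0.32 for mutant replicates 1, 3 and 4, so 1 array dominated the weighted mutant mean.

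**Figure D2:**
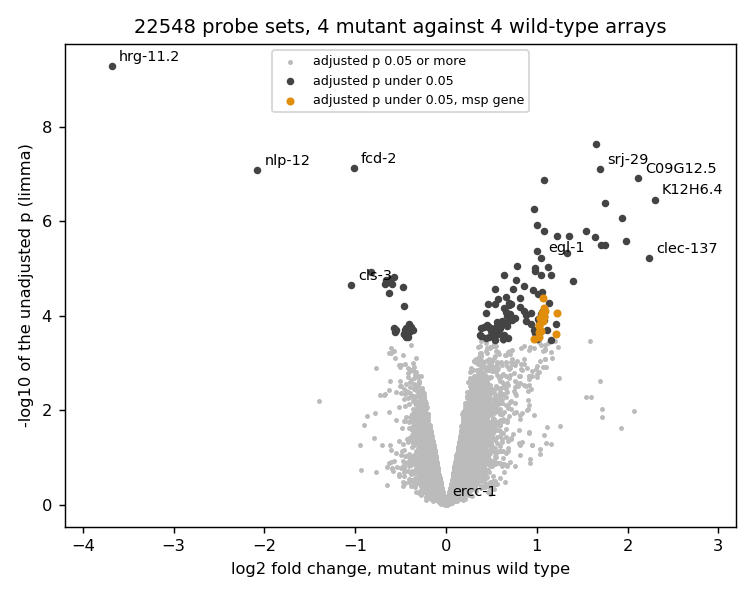
Each point is 1 of 22548 probe sets, with the log2 fold change of mutant minus wild type on the x axis and the -log10 of the unadjusted limma p on the y axis. Dark and orange points are the 150 calls, 121 of them to the right of 0, the orange ones are msp genes, and hrg-11.2 lies farthest to the left at -3.68.

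Part of the sperm list was higher in the mutant, and the genes called in it were mainly msp genes. Of 61 genes in the sperm list, 21 rose and 0 fell, and 44 rose and 1 fell when p was adjusted over the list alone. Of these, 18 were among the 23 measured msp genes, which encode the major sperm proteins, with a median of 2.1-fold over the family and all 23 above wild type. The levels of msp-49, msp-50 and msp-77 were 2.09-fold, 2.11-fold and 2.13-fold higher (adjusted p = 0.0189, 0.0254 and 0.0277), and ssp-10 was 1.72-fold higher (adjusted p = 0.00795). The others that rose were ssp-37 and nspd-9, outside the naming rule and named after their values were seen. Outside the msp family 35 of 38 genes lay above wild type, with a median log2 change of 0.45 and 3 called. Of these 38 genes, 18 were read by _x_at or _s_at probe sets. Medians were 0.924 over 6 nspd genes, 0.586 over 14 ssp, ssq and msd genes and 0.689 over 2 gsp genes. None of the 16 spe and fer genes, which act in sperm development and function, passed, and their median was 0.047 on the log2 scale. Their median level was also the lowest of these subsets, 6.74, near the bound of 6.42 for dim probe sets. It was 11.49 for msp, 8.96 for nspd, 7.71 for ssp, ssq and msd, and 7.38 for gsp genes. Whether the low level hid a change in spe and fer genes was not tested, so they are no clear contrast to the msp genes. The list's mean log2 change was 0.67 (camera adjusted p = 3.65e-31 with the preset correlation, adjusted p = 0.355 with an estimated correlation). It was 0.27 over the 21 genes left without probe sets of the suffix _x_at or _s_at (adjusted p = 0.000613; adjusted p = 0.577 with an estimated correlation). All msp probe sets carry a suffix that marks possible matches to several transcripts. The list's score was 1.13 above the wild-type mean on mutant replicate 4, against 0.53, 0.50 and 0.51 on mutant replicates 1 to 3. The number of list members that rose was 36 without mutant replicate 4, 11 and 7 without mutant replicate 1 and 2, and 1, ssp-10, without any 1 of the wild-type replicates, where the median msp change stayed between 2.03-fold and 2.14-fold. Adjusted p was then 0.0642 to 0.11 for msp-49, 0.0845 to 0.121 for msp-50 and 0.0881 to 0.123 for msp-77.

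Genes of the male tail and male neurons, 12 in number, were examined beside the sperm list because cultures of mixed stage can hold males. Of these cwp-2 rose (log2 difference 0.68, adjusted p = 0.029), and 2 rose when p was adjusted over the list alone. The values for cil-7, pkd-2 and cwp-5 were 0.42, 0.18 and 0.14 (adjusted p = 0.18, 0.692 and 0.636); pkd-2 read 0.072 without mutant replicate 4. As a set the list passed with the preset correlation (adjusted p = 0.0443) and not with an estimated correlation (adjusted p = 0.642). The set's call ended without wild-type replicate 1, 2 or 4 (adjusted p from 0.0543 to 0.12) and without mutant replicate 3 or 4 (0.086 and 0.361). It ended also after quantile normalization (0.0562), without dim probe sets (0.772), without _x_at and _s_at probe sets (0.215), with a trended robust variance (0.0598) and with array weights (0.157), and the mean of 0.15 was 0.064 after median centring, 0.068 without dim probe sets and 0.102 without mutant replicate 4. The call of cwp-2 ended without any 1 wild-type replicate (0.0876 to 0.126), and after median centring (its log2 difference was then 0.59).

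**Figure D3:**
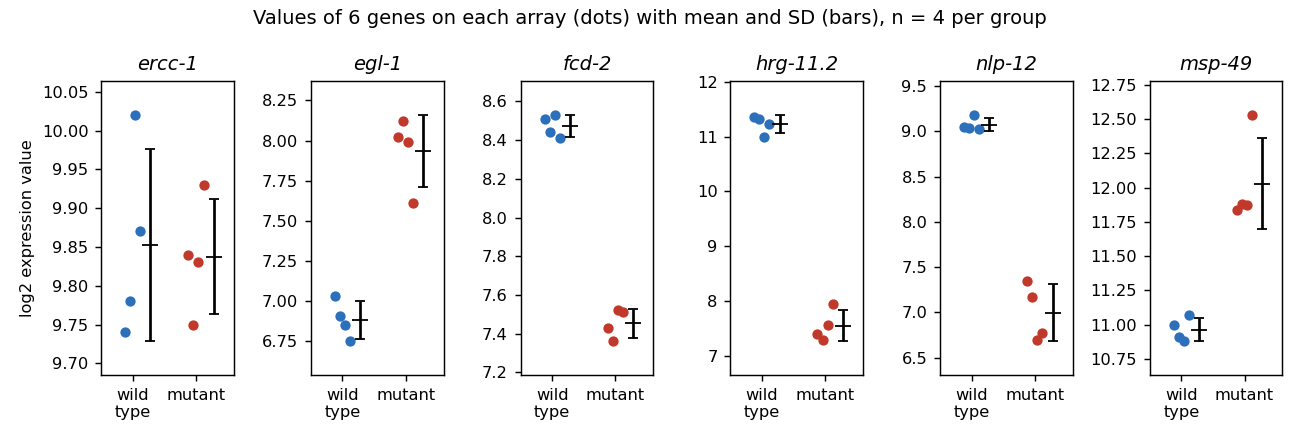
Log2 expression values (y axis, a separate scale for each gene) of ercc-1, egl-1, fcd-2, hrg-11.2, nlp-12 and msp-49 on the 4 wild-type (blue) and 4 mutant (red) arrays, with bars for the mean and SD. The groups overlap for ercc-1 (9.84 against 9.85) and do not overlap for the other genes.

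In the DNA repair and cell death lists single genes moved. In the list of other DNA repair and damage checkpoint genes, fcd-2 fell and the other 49 of 50 did not pass; xnd-1, nth-1 and atm-1 read -0.16, -0.17 and 0.21 (adjusted p = 0.534, 0.54 and 0.597). In the apoptosis and corpse clearance list, egl-1, which encodes the BH3-only activator of programmed cell death, rose 2.07-fold (log2 difference 1.05, SE 0.116, adjusted p = 0.00579) and stayed past the threshold in all 8 fits that left out 1 array. The other 23 of 24 genes did not pass. The log2 differences of nuc-1, ced-3 and crn-1 were 0.30, 0.16 and -0.13 (adjusted p = 0.296, 0.578 and 0.666); a second ced-3 probe set read -0.38, and crn-1 read -0.079 without mutant replicate 2. The apoptosis list did not pass (mean 0.057, adjusted p = 0.928). The direction of its test turned down under quantile normalization, where its mean was 0.009, and its mean turned to -0.033 under median centring. Of 13 nucleotide excision repair genes 0 passed, with csa-1 and xpc-1 at -0.27 and -0.41 (adjusted p = 0.232 and 0.682), and xpc-1 at -0.62 without wild-type replicate 1.

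The insulin-like signalling list, which regulates lifespan in this worm through the factor DAF-16, passed as a set (mean 0.13, adjusted p = 0.00349; adjusted p = 0.355 with an estimated correlation; fry adjusted p = 0.0429), with a mean of 0.038 after median centring and 0.070 after quantile normalization. Of 35 genes ins-31, an insulin-like peptide, rose (0.64, adjusted p = 0.0426), and 1 also rose when p was adjusted over the list alone. The values of ins-7, pdk-1 and ins-30 were 0.56, 0.32 and 0.26 (adjusted p = 0.243, 0.233 and 0.33), and 4 further pdk-1 probe sets lay between 0.0075 and 0.29. The call of ins-31 ended when any 1 mutant replicate (adjusted p from 0.0517 to 0.0753) or any 1 wild-type replicate (0.119 to 0.162) was left out, and after quantile normalization (log2 difference 0.54) or median centring (0.55), and without _x_at and _s_at probe sets (adjusted p = 0.062). Of 20 measured targets in the DAF-16 class 1 list, which are raised when insulin-like signalling is low, 0 passed (mean 0.19, adjusted p = 0.205; adjusted p = 0.914 with an estimated correlation), with far-3 and gst-4 at -0.73 and -0.33, the latter -0.22 without wild-type replicate 3. That list's mean was 0.026 without mutant replicate 1 (adjusted p = 0.894) and 0.40 without mutant replicate 4, where it passed (adjusted p = 1e-04), as it did after median centring (mean 0.10, adjusted p = 0.016) and with array weights (mean 0.31, adjusted p = 0.0219). With an estimated correlation these 3 calls ended (adjusted p = 0.651, 0.702 and 0.603). Of 12 class 2 targets 0 passed as genes, with nuc-1 and dod-22 at 0.30 and 0.37 (dod-22 at 0.24 without mutant replicate 4), and the set passed (mean 0.19, adjusted p = 0.0359; adjusted p = 0.355 with an estimated correlation). This set's call ended without mutant replicate 1 or 4 (0.112 and 0.182) and without wild-type replicate 1 or 4 (0.109 and 0.0699). It also ended without _x_at and _s_at probe sets (0.0606) and with array weights (0.098), and the mean was 0.096 after median centring.

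In the oxidative stress and glutathione list gst-16, a glutathione S-transferase, fell by 0.39 on the log2 scale (adjusted p = 0.0391), also when p was adjusted over the list alone, and the other 65 of 66 did not pass. The values of gst-19, trxr-2 and gst-10 were -0.25, -0.24 and -0.31 (adjusted p = 0.193, 0.247 and 0.336). The set passed with a mean of -0.011 (adjusted p = 0.0118; adjusted p = 0.642 with an estimated correlation), a call that ended without mutant replicate 3 or wild-type replicate 3 (0.0786 and 0.0914), where the mean was 0.017 and 0.023. It ended too without _x_at and _s_at probe sets (0.0606), and the mean was -0.101 after median centring, -0.060 after quantile normalization, 0.004 without dim probe sets and 0.003 with array weights. Without mutant replicates 1 and 4, left out singly, it was -0.036 and -0.017, and without wild-type replicates 1, 2 and 4 -0.025, -0.022 and -0.021. The call of gst-16 ended without any 1 mutant replicate (0.0506 to 0.105) or any 1 wild-type replicate (0.0997 to 0.16), and with a trended robust variance (0.0542).

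Detoxification genes were examined in a list of their own. Among 126 cytochrome P450 and UDP-glucuronosyltransferase genes, cyp-35D1 rose (0.69, adjusted p = 0.0225) and ugt-64 fell, against 3 and 1 when p was adjusted over the list alone; ugt-43 and cyp-14A5 read 0.37 and 0.55 (adjusted p = 0.0735 and 0.0796). Without mutant replicate 4, 2 genes of that list rose. The call of cyp-35D1 ended without any 1 wild-type replicate (0.0511 to 0.114), and after quantile normalization (log2 difference 0.62) or median centring (0.60). As a set that list did not pass (camera adjusted p = 0.795). Its median and mean were 0.029 and 0.043. The direction of its test was down relative to the other genes, with a mean of 0.05 over all genes. Of 54 heat shock and unfolded protein response genes 0 passed, with hsp-43 and dnj-8 at 0.49 and 0.19 (adjusted p = 0.0978 and 0.369); the list's median, -0.004, and mean, 0.064, differed in sign, and its adjusted p was 0.506 with its direction down. The mean turned to -0.026 after median centring, and that of the P450 and glucuronosyltransferase list to -0.047, and to -0.015 after quantile normalization and -0.001 without mutant replicate 1. Other probe sets of dnj-8 read 0.015 and -0.063.

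Among 73 innate immunity genes, fipr-16 and fipr-17 rose and 0 fell, and 3 rose and 1 fell when p was adjusted over the list alone. The probe sets of fipr-16 and fipr-17 carry the suffixes _x_at and _s_at, so each can match several transcripts. The values of spp-23 and spp-10, saposin-like proteins, were -0.45 and 0.31 (adjusted p = 0.0979 and 0.141), and other spp-10 probe sets read 0.32 and 0.26. The set passed with a mean of 0.20 (adjusted p = 0.00178; adjusted p = 0.642 with an estimated correlation). The mean was 0.132 without mutant replicate 1, whose score was 0.401 against 0.234, 0.101 and 0.061 on the other mutant arrays, and 0.109 after median centring, where the median was 0.020. Without mutant replicate 3, 4 members rose.

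Lists of somatic tissues did not move alike on the 4 mutant arrays. Mutant replicate 3 scored below the wild-type mean for neurons (-0.068), body wall muscle (-0.125) and cuticle collagens (-0.098), and mutant replicate 4 for neurons (-0.054). The pharynx list had a mean of 0.26 (adjusted p = 2.07e-07; adjusted p = 0.355 with an estimated correlation), 0 of 34 genes passed over all probe sets and 7 rose when p was adjusted over the list alone, and pha-4 and phat-8 read 0.28 and 0.63, with 0.11 for the other pha-4 probe set. The means of the neuron list (62 genes) and the body wall muscle list (38 genes) were 0.16 and 0.17 (adjusted p = 0.00349 each; adjusted p = 0.737 each with an estimated correlation), with 0 genes past in either; flp-13, unc-18, atn-1 and unc-27 read 0.33, 0.23, 0.39 and 0.21, and the other unc-18 probe set 0.02. Both calls ended without mutant replicate 1 (adjusted p = 0.509 each), whose scores were 0.49 and 0.51 above the wild-type mean, and the means were then 0.043 and 0.064. Without mutant replicate 3 the body wall muscle mean was 0.274. Cuticle collagens had a mean of 0.11 over 146 genes (adjusted p = 0.00711; adjusted p = 0.875 with an estimated correlation), with 0 past and col-150 and col-129 at 0.32 and 0.72; the second col-150 probe set read -0.0075, and col-129 was 0.48 without mutant replicate 4. That call ended without mutant replicate 4 (mean 0.050, adjusted p = 0.792), its mean was 0.183 without mutant replicate 3, and it ended without wild-type replicate 1 (0.109). After median centring the means were 0.065 for neurons, 0.084 for body wall muscle, 0.169 for pharynx and 0.023 for collagens, after quantile normalization 0.088 for neurons and 0.060 for collagens, and with array weights 0.25 for neurons, and the body wall muscle call ended without _x_at and _s_at probe sets (0.0606). The intestine, moulting, vitellogenin and embryonic lists did not pass (adjusted p = 0.577, 0.661, 0.764 and 0.979), except that moulting passed with array weights (adjusted p = 0.0346; adjusted p = 0.603 with an estimated correlation), with gem-4 and asp-1 at 0.37 and 0.15, nekl-2 and ptr-25 at 0.34 and 0.31, vit-2 and vit-5 at 0.13 and 0.07, and elt-7 and pes-1 at 0.33 and -0.17. Without mutant replicate 1 gem-4 read 0.228, and without wild-type replicate 3 vit-2 read 0.074. After median centring the signs of vit-5 (-0.023) and of the means of all 4 lists turned: vitellogenins (-0.053), embryonic (-0.043), moulting (-0.037) and intestine (-0.007). The moulting mean also turned after quantile normalization (-0.009) and without mutant replicate 1 (-0.014), and the vitellogenin mean without wild-type replicate 3 (-0.007).

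Germline, cell division and housekeeping lists passed as sets with the preset correlation (adjusted p from 0.00602 to 0.0359, the 2 DNA repair sets included) and not with an estimated correlation (adjusted p from 0.355 to 0.737). These calls are relative to the other genes, with a mean of 0.05 over all genes, and do not by themselves show a fall from wild type. Apart from fcd-2, none of the lists' genes passed over all probe sets, and the lists' means depended on the scaling of the arrays. The means were -0.047 for meiosis and synapsis (syp-3 and htp-1 at -0.20 and -0.14), -0.029 for germline maintenance (glp-1 and sygl-1 at -0.15 and -0.19), -0.021 for oocyte and early embryo (cey-3 and perm-2 at -0.13 and 0.08, the latter -0.013 after median centring) and -0.030 for cell cycle and DNA replication (cdt-1 and rfc-4 at -0.36 and -0.12). They were -0.019 for ribosomal proteins (rpl-32 and rpl-41.2 at -0.08 and -0.07), -0.031 for the proteasome (pas-4 and pbs-4 at -0.12 and -0.10) and -0.029 for mitochondrial respiration (asg-1 and clk-1 at -0.16 and -0.16). The nucleotide excision repair and other DNA repair sets had means of -0.066 and -0.030. After median centring the means of these 9 lists lay between -0.109 (ribosomal proteins) and -0.156 (nucleotide excision repair), with meiosis and synapsis at -0.137 and the proteasome at -0.121. All 9 passed there with the preset correlation and 0 with an estimated correlation (adjusted p from 0.299 to 0.719). After quantile normalization they lay between -0.015 (ribosomal proteins) and -0.113 (nucleotide excision repair). Array weights moved other DNA repair to -0.064, germline maintenance to -0.076, nucleotide excision repair to -0.036, mitochondrial respiration to -0.019 and ribosomal proteins to -0.005. The ribosomal call ended after quantile normalization (adjusted p = 0.574), and without _x_at and _s_at probe sets 6 calls ended: nucleotide excision repair (0.24), germline maintenance (0.0885), oocyte (0.537, where its mean turned to 0.018), mitochondrial respiration (0.13), proteasome (0.133) and ribosomal proteins (0.0874). Nucleotide excision repair ended with array weights (0.157) and oocyte with the mean over all probe sets of a gene (0.104). Leaving out 1 array moved the mean of mitochondrial respiration to -0.067 (mutant replicate 1), -0.003 (mutant replicate 3) and -0.016 (mutant replicate 4), that of ribosomal proteins to -0.008 (mutant replicate 3), and that of the proteasome to -0.018 and -0.047 (mutant replicates 1 and 4). It moved other DNA repair to -0.013, -0.017 and -0.052 (mutant replicates 1, 2 and 3), nucleotide excision repair to -0.038 and cell cycle to -0.019 (mutant replicate 4), and germline maintenance to -0.010, -0.048 and -0.044 (mutant replicates 2 and 3, wild-type replicate 3). The oocyte mean moved to -0.013, -0.041 and -0.005 without mutant replicate 1, 3 and 4, and to -0.013, -0.045 and -0.011 without wild-type replicate 2, 3 and 4. Without mutant replicate 1 the calls of 7 of them ended (adjusted p from 0.118 to 0.227), all but those of ribosomal proteins and mitochondrial respiration. Calls also ended without mutant replicate 2 for germline maintenance and other DNA repair (0.148 and 0.0553), without mutant replicate 3 for mitochondrial respiration (0.124), and without mutant replicate 4 for cell cycle, mitochondrial respiration, nucleotide excision repair and oocyte (0.0695 to 0.225). Without wild-type replicate 1 or 4 those of germline maintenance and oocyte ended (0.0573 to 0.12), and without wild-type replicate 2 those of 5 lists (0.0528 to 0.187). The histone, fatty acid and glycolysis lists did not pass (adjusted p = 0.506, 0.577 and 0.764), with his-42 and his-70 at 0.26 and 0.32, acs-21 and far-6 at 0.38 and 0.37, and tps-2 and pfk-1.2 at 0.23 and 0.15. Their means of 0.072, 0.063 and 0.059 turned to -0.018, -0.027 and -0.031 after median centring, and that of glycolysis to -0.003 without mutant replicate 1. Single genes moved as well: asg-1 to -0.10 without mutant replicate 4, sygl-1 to -0.106 without mutant replicate 2, rpl-32 to -0.048 without mutant replicate 3, and clk-1 and rfc-4 to -0.089 and -0.068 without wild-type replicate 3. The other probe sets of asg-1 and perm-2 read -0.135 and 0.038.

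Of the 30 lists, 19 passed with the preset correlation, 9 up and 10 down relative to the other genes, 0 with an estimated correlation (lowest adjusted p = 0.355; limma's camera), and 1 by the directional and 8 by the mixed test of fry. The number was 9 without mutant replicate 1.

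**Figure D4:**
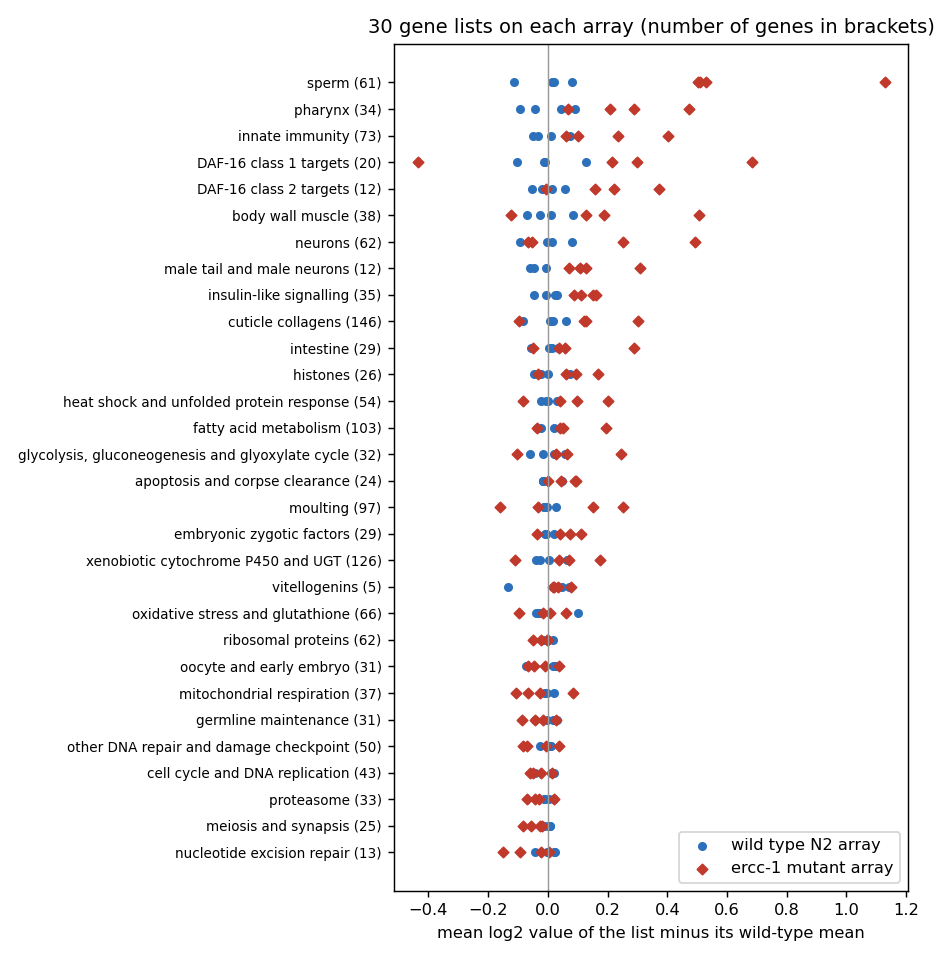
Mean log2 value of each of 30 gene lists on each array, minus the list's mean over the wild-type arrays (x axis), with the number of genes in brackets. The sperm list lies highest, with mutant arrays (red diamonds) at 0.50 to 1.13, and the spread of the mutant arrays is wide for DAF-16 class 1 targets, from -0.44 to 0.68.

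Called genes were more frequent on chromosome IV. There 29 of 2666 genes passed, 27 higher and 2 lower, an odds ratio of 1.83 against the other chromosomes (Fisher's exact test, two-sided, adjusted p = 0.0398). The odds ratio on chromosome II was 1.65, with 30 of 3013 genes (Fisher's exact test, adjusted p = 0.0786). Of 370 genes within 1 Mb of ercc-1, 0 passed, against 115 of 16695 elsewhere (Fisher's exact test, p = 0.185). The excess on chromosome IV was not past the threshold at a looser adjusted p for genes of 0.1 (adjusted p = 0.169), nor, by the exact test, without mutant replicate 1 or 2 (0.154 and 0.597) or wild-type replicate 1, 2, 3 or 4 (0.616, 0.31, 0.747 and 0.354), and 2 chromosomes passed without mutant replicate 4.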

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

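All tests of explanations in this part were chosen after the results were seen. Of 246 groups of 4 arrays examined, for the named genes and the lists, 22 held 1 array whose gap to the nearest other exceeded a critical share of the group's range, where chance marks about 1 group in 20.

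Mutant replicate 4 stood apart for sperm genes. It read highest of the mutant arrays for msp-49, msp-50 and msp-77 (gap 0.942, 0.945 and 0.948 of the range) and for the sperm list (0.96), where it scored 1.13 against 0.50 to 0.53. It also read lowest for vit-5 (0.857).

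The higher sperm-list mean in the mutant was weighed against shared probe signal, more males and a larger share of larvae. Signal shared between near-identical msp copies would act on the arrays of both groups, and so would not by itself set them apart. It can make 1 rise count as many, so how many of the 23 msp genes rose, at 1.89-fold to 2.34-fold, cannot be told. Genes outside the msp family were therefore looked at without the suffixes _x_at and _s_at. The 20 sperm-list genes outside the msp family with probe sets of their own had a median change of 0.141, and 1 was called. Their median level was 6.76 on the log2 scale, against 11.49 for the msp genes. Whether that lower level made their change smaller was not tested. The arrays were not centred here, and median centring lowers every log2 difference by 0.09. The mean of the 20 genes was higher in every mutant array, also uncentred (exact permutation p = 0.0286, the smallest that 70 assignments allow). Their median lay above 99.42% of 10000 random lists. Those lists were drawn gene by gene, while sperm-list genes moved together (estimated correlation 0.677), so that percentile is no support. With an estimated correlation, the 21 sperm-list genes left without _x_at and _s_at probe sets did not pass (camera adjusted p = 0.577). More males among the mutant worms remains open, since the male list had a median of 0.115 over 12 genes and its call ended with an estimated correlation. That list is a weak test, since only 6 of its 12 genes remained without dim probe sets. The groups did not overlap for cwp-2 and cil-7, with wild-type means of 5.19 and 4.505, under the dim bound of 6.42. They overlapped for cwp-5 and pkd-2. A larger share of larvae is not settled, since 2 mutant arrays had a moulting-list mean above every wild-type array and 2 below. The moulting score did not follow the sperm score. Mutant replicates 3 and 4 scored -0.162 and -0.032 for moulting and 0.51 and 1.13 for sperm, while their cuticle collagen scores were -0.098 and 0.301. An effect of the mutation on sperm production was not tested, nor whether the mutation itself changes the share of males or larvae.

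Wild-type replicate 3 was the array set apart most often. It read highest for gst-4 (0.896), rfc-4 (0.85), col-150 (0.9), pfk-1.2 (0.846) and rpl-41.2 (0.857) and lowest for vit-2 (0.833). Its list score was lowest for other DNA repair (0.914), cell cycle (0.859) and oocyte (0.865), and highest for oxidative stress (0.923) and embryonic factors (0.862).

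Other arrays were set apart for single results. Wild-type replicate 1 was highest for the apoptosis list (0.984) and lowest for far-6 (0.846). Wild-type replicate 2 was lowest for K12H6.4 (0.956) and wild-type replicate 4 for srj-29 (0.875). Mutant replicate 2 was lowest for C09G12.5 (0.887), and mutant replicate 1 highest for elt-7 (0.852).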

How the results depend on the processing

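Leaving out mutant replicates 1 and 4 together, and leaving out each array in the chromosome test, were chosen after seeing the data. The causes of the changes below were not tested, except that fits with fewer arrays or probe sets have less to test. The falls of hrg-11.2, nlp-12 and fcd-2, the rise of egl-1 and the 10 largest rises kept their direction and stayed past the threshold without any 1 array. The falls were read by _s_at probe sets and so were not in the fit without _x_at and _s_at probe sets. Without 1 array, 29 to 268 probe sets passed (26 to 231 higher, 3 to 37 lower), 9 to 18 lists and 0 to 2 chromosomes, and the similarity difference ran from 0.00039 to 0.00348. With array weights 1423 probe sets passed (1155 higher, 268 lower), without probe sets of the suffix _x_at or _s_at 46 (39 higher, 7 lower) with 9 lists, at an adjusted p of 0.1 246, and at 2-fold or more 62. The array weights rested the mutant mean largely on replicate 2 (weight 5.05, against 0.32 to 0.62 for the other mutant arrays). Median centring left 75 higher. Without mutant replicates 1 and 4, 16 were lower, 10 lists passed, and the calls of cwp-2, F19B10.2, ins-31 and gst-16 ended (adjusted p = 0.0661, 0.0843, 0.141 and 0.181). With an estimated correlation 0 lists passed, with the directional test of fry 1 and with its mixed test, which counts moves both ways, 8, and at an adjusted p of 0.1 for genes 0 chromosomes. The odds ratio near ercc-1 was 1.09 within 3 Mb, against 0 within 1 Mb.

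With the replicate number as a block 125 probe sets passed (13 of them lower). The calls of F19B10.2 (adjusted p = 0.0512), ins-31 (0.0614), cwp-2 (0.0692), cyp-35D1 (0.0733) and gst-16 (0.096) ended in that fit, and phat-8 passed (0.0333). Arrays of the same number deviated together with correlations of 0.473, 0.014, 0.04 and 0.201, and only replicate 1 correlated best with its own number.

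Some lists that did not pass, and some that did, changed the direction of their test. The named genes whose value moved by over 1.5 times numbered 30 after median centring, 14 with array weights, 5 after quantile normalization and 11 without mutant replicates 1 and 4, where xpc-1, dod-22 and pkd-2 read -0.035, 0.080 and 0.055. The apoptosis mean was 0.009 after quantile normalization, -0.033 after median centring, 0.058 without dim probe sets, 0.051 without _x_at and _s_at, 0.052 with weights, 0.057 with the block and 0.044 over all probe sets of a gene. The embryonic mean was -0.011 after quantile normalization. Under median centring the means were -0.043 (embryonic), -0.047 (xenobiotic), -0.053 (vitellogenins, -0.002 with weights) and -0.031 (glycolysis), with perm-2 at -0.013 and vit-5 at -0.023. Without mutant replicates 1 and 4 they were 0.068 (heat shock), 0.054 (xenobiotic), 0.018 (embryonic), 0.014 (collagens), -0.005 (moulting), 0.031 (body wall muscle) and 0.002 (intestine).

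Without 1 array, means ran from 0.044 to 0.076 (apoptosis), 0.025 to 0.075 (embryonic), 0.019 to 0.096 (fatty acid), -0.003 to 0.113 (glycolysis), 0.018 to 0.112 (heat shock), 0.041 to 0.107 (histones), 0.014 to 0.127 (intestine), -0.014 to 0.124 (moulting), -0.007 to 0.061 (vitellogenins) and -0.001 to 0.094 (xenobiotic), and ercc-1 from -0.053 to 0.041. No background level is known, so the reliability of dim probe sets could not be set against it.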

Other observations

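All tests in this part were chosen after the results were seen. Among 390 gene families tested for called genes by name, the C-type lectin family held 8 rises among 220 measured members and 0 falls (odds ratio 5.92, Fisher's exact test, adjusted p = 0.0233). Besides clec-137 and clec-219, these were clec-197 (2.34-fold), clec-190 (2.16-fold), clec-138 (1.81-fold), clec-94 (1.77-fold), clec-99 (1.69-fold) and clec-96 (1.56-fold), the last 6 named after their values were seen. Of the 8, clec-94, clec-96 and clec-99 lie within 3 Mb of ercc-1, where 8 of 1098 genes were called (0.73%, against 0.67% elsewhere). The family test counts them as independent, and whether they moved together was not tested. The median over the family was 0.087 on the log2 scale. The family tests were not repeated with arrays left out. Without any 1 wild-type replicate, 26 to 33 genes in all were called, against 115 with all arrays. The msp family passed as well (18 of 23, Fisher's exact test, adjusted p = 2.46e-33), and the fipr and ssp families, with 2 of 8 each, did not (Fisher's exact test, adjusted p = 0.119 each). Without any 1 wild-type replicate 0 msp genes were called. The msp probe sets can match several transcripts, so the test may not count independent genes.

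The 4 genes at least 2-fold lower in the mutant were weighed as possible strain differences. Variants linked to ercc-1 that lie at the affected gene are argued against as the cause of all 4 falls. This is because 3 of the genes, hrg-11.2, fcd-2 and cls-3, lie on other chromosomes. The position of the genes cannot test a linked variant that acts on genes elsewhere, so that stays open. For nlp-12, 8.19 Mb from ercc-1 on the same chromosome, a linked variant cannot be told apart from an effect of the mutation, since the crosses behind the strain are not known. Deletions spanning several genes are argued against too: among the 16 measured neighbours the lowest log2 difference was -0.193 for tax-4, beside cls-3, and 0 passed the threshold. Unlinked variants confined to each gene, or a loss of probe binding through a variant, stay open and were not tested. That these falls follow from the loss of ERCC-1 may be stated only as a hypothesis.

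The excess of called genes on chromosome IV may come from sperm genes located there. With the sperm list left out the odds ratio was 1.29 (Fisher's exact test, p = 0.319) against 1.83 with it. The list was fixed without regard to position, but the test does not tell whether the remaining excess is 0.

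Splitting the 8 arrays in the 34 other ways gave at most 0 called probe sets, so only 1 of 35 splits, the real one, reached 150. This argues against a chance split of these 8 arrays for that count, with 1 of 35 the smallest share possible. The labels do not say that replicates came from separate cultures. If they did not, the splits cannot test a chance difference between cultures. For gene lists with the preset correlation chance stays open: 2 of 35 splits called 19 or more, and the highest of the other splits called 20.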
